A study of Populus tremula x Populus alba with 3 samples.

How the data were processed

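RNA was sequenced from apical buds of the hybrid poplar clone INRA 717-1B4, a cross of Populus tremula and Populus alba that is widely used for transformation. The labels give 3 libraries. One came from wild type, and 2 came from RNA interference lines against PtaDML10, a gene named after the DEMETER-like DNA demethylases, enzymes that remove methylated cytosine from DNA. These lines are KD2 (replicate 1) and KD5 (replicate 2). Per the labels' protocols, 15 buds were taken from 15 plants of each genotype, and whether the buds were pooled was not stated. Libraries were made with a directional kit.

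Per the labels, plants grew for 4 weeks in long days of 16 h at 21 °C and then for 12 weeks in short days of 8 h at 19 °C. They were held at 4 °C for 4 weeks and returned to long days, and buds were collected before visible bud break.

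The deposited count table holds raw whole-number counts for 41335 poplar gene identifiers in 1 column per library. The submitters' processing notes name FastQC, TopHat and edgeR. Their versions, the genome build, the annotation and the counting program are not given in the sources used here. The authors' deposited table lists 2151 genes with a log2 fold change of the KD lines against wild type. It also gives an average log2 CPM. The p-values and adjusted p-values (FDR) in the table are the authors', computed before deposition per the file headers, and the largest FDR listed is 0.0499. For 2010 of these genes the authors' deposited table adds an Arabidopsis locus, for 847 a symbol and for 1805 a description. No other annotation was used here, so genes outside that table carry no name. The identifier of PtaDML10 and of 13 other genes was taken from published poplar naming, which the files do not pair with these identifiers, apart from LHY1.

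Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 23089. Libraries were scaled by TMM, with factors of 0.904 for wild type, 1.06 for KD2 and 1.044 for KD5. CPM values given here are counts scaled by library size and TMM factor. The quasi-likelihood F-test compared both RNAi libraries with the wild type library, two-sided, and genes with a Benjamini-Hochberg adjusted p below 0.05 are described as called. This design leaves 1 residual degree of freedom. The spread comes from KD2 against KD5, and the single wild type library is assumed to vary like them. The common dispersion was 0.013, a coefficient of variation of 11.4%. The prior degrees of freedom were infinite, so every gene took its dispersion from the trend. The p-values measure the spread between these libraries, which differ in line as well as in sampling.

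Log2 ratios of 1 library to another used a prior count of 2 and have no test. Intervals for counts are exact Poisson intervals at 95%, and floors are 3 counts per library, or 0.488 CPM in wild type, 0.63 CPM in KD2 and 0.615 CPM in KD5. Both cover counting error only. The fit was tested on simulated counts in which 100 genes changed by 2-fold and 100 by 4-fold. It recovered 45% of the former and 88% of the latter with 9 false calls among 22856 genes, and it called 0 genes when none was changed. All 3 simulated libraries shared 1 dispersion, so this does not test whether wild type varies like the RNAi libraries.

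The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 25 lists were matched on Arabidopsis locus, symbol or description. Since these exist for the authors' listed genes alone, the lists are counts among genes that the study had already selected on these libraries, the background is not annotated, and no enrichment test was made. The list of cytosolic ribosomal proteins is called ribosomal proteins here, since its name match also takes plastid ones. The count adjusted over the list alone is for that reason not independent evidence. Added after seeing the data were 7 further lists and a comparison of each list's median with 10000 random lists. The random lists had the same size, were matched on mean expression and came from the listed genes with an Arabidopsis locus. They could draw the list's own members, which pulls the percentile of a large list toward the middle. The percentiles describe these libraries and take no account of correlation between genes. The authors' own settings and a loess normalization on abundance were also added.

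Named genes are of 4 kinds. The first is PtaDML10, and the second the 13 genes given by identifier. The third holds the 6 called genes with the largest change in each direction among described genes with a mean of at least 5 CPM and both RNAi libraries on the same side of wild type. The fourth holds the called members of each list with the smallest adjusted p, at most 3 per list, or 4 where at least 15 were called. Alternatives covered 3 other scalings, 2 other filters, other tests including DESeq2 1.42.0 and limma 3.58.1, and stricter thresholds. Without 1 RNAi library only a comparison of 1 library with 1 is left, which gives fold changes and no calls.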

Results

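Gene expression was measured in poplar apical buds collected before bud break from wild type (n = 1 library) and from RNAi lines against PtaDML10 (n = 2 libraries, KD2 and KD5). The wild type library held 6829583 counts, KD2 4509887 and KD5 4692056, and between 28656 and 28868 genes had at least 1 count in a library. The 10 most abundant genes took 3.8% of the counts in wild type, 3.66% in KD2 and 3.67% in KD5. Wild type has no replicate, so its values carry no SD. Values for the RNAi libraries are means ± SD of 2 libraries.

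The targeted gene was examined first. The PtaDML10 locus, Potri.010G234400, stood at 9.59 CPM in wild type (59 counts), 13.2 CPM in the library labelled KD2 (63 counts) and 17.01 CPM in the library labelled KD5 (83 counts). Both RNAi libraries lay above wild type, against the direction of a knockdown, although the change was not called (log2 fold change 0.66, SE 0.31, edgeR quasi-likelihood adjusted p = 0.15). Counting error alone gave a ratio of RNAi to wild type of 1.58, with an exact 95% interval from 1.16 to 2.17. With libraries scaled by size only, the gene was called higher, at a log2 fold change of 0.87. The labels KD2 and KD5 were therefore not borne out at this locus, and each direction given here is that of the libraries so labelled. The identifier rests on published naming that the files do not pair with it, and gene counts do not separate transgene reads from those of the native gene. The list of DNA demethylases had 0 members in the authors' deposited table.

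**Figure D1:**
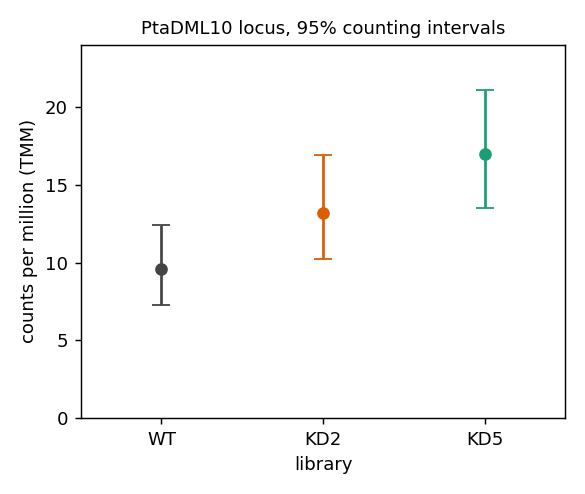
CPM (TMM-scaled) of the PtaDML10 locus in each of the 3 libraries, with exact Poisson 95% intervals that cover counting error only. The wild type library is at 9.59, the library labelled KD2 at 13.2 and the library labelled KD5 at 17.01.

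The main comparison asked which genes differ in unopened buds between the RNAi lines and wild type. Among the genes of the authors' deposited table, most members of the lists for histones, ribosomal proteins, photosynthesis, flavonoid synthesis and cell wall loosening were called lower in the libraries labelled KD2 and KD5, and most AP2/ERF transcription factors and genes with an organelle-genome match were called higher. These genes had been selected on the same libraries, and 65.7% of the 1813 called ones with an Arabidopsis locus were lower, so the counts are not independent evidence of direction and no enrichment test was made. Against random lists matched on expression, the ribosomal, photosynthesis and cell wall medians lay within range, at the 12.42, 8.22 and 5.99 percentiles. Those of the histone and flavonoid lists lay at 0.01 and 0.25, and those of the AP2/ERF and organelle lists at 99.99 and 100. Of 23089 genes tested, 3014 were called, with 1155 higher and 1859 lower (38.3% higher). With libraries scaled by size only, 3004 were higher and 976 lower (75.5% higher), and with upper quartile scaling 1393 were higher and 1585 lower. Size-only scaling moved the median log2 fold change of the tested genes from 0.02 to 0.24. Without a filter on low counts edgeR's quasi-likelihood test called 0 genes, with 5051 at an unadjusted p under 0.05, and DESeq2 called 595. Loess normalization left 1175 calls, and requiring at least 2-fold left 924, 50.8% of them higher. Of the 31 list counts, 22 moved by over 1.5 times with loess normalization on abundance, added after seeing the data, 23 with DESeq2 and 31 without a filter. Lower calls lay at higher expression, with a median of 62.4 CPM against 21.1 CPM for higher calls, and among genes over 256 CPM 256 were called lower and 3 higher.

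Among described genes with at least 5 CPM, the largest fitted rise was in Potri.017G074500, which matches the chloroplast ATP synthase subunit C gene. It had 0 counts in wild type and 18.1 ± 5.29 CPM (SD, n = 2) in the RNAi libraries, at least 37.1-fold higher against the wild type floor of 3 counts. Its rank over the next genes is therefore not settled. Potri.010G052900, a Ycf1 match, had 1 count in wild type against 94 in KD2 and 90 in KD5, a ratio of 117 with a counting interval from 20.8 to 4660. Potri.001G415100, a terpene synthase (TPS21), and Potri.013G121900, an O-methyltransferase, also had 0 counts in wild type, and rested on KD5. TPS21 had 2 counts in KD2 and 78 in KD5, and the methyltransferase had 1 and 77. Potri.005G163600, the match of EXO, rose from 1.63 CPM to 16.2 CPM in KD2 and 20.7 CPM in KD5. Potri.018G145200, a ribosomal protein L11 family member, rose from 2.6 CPM to 13.02 and 29.51 CPM.

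The largest fall was in Potri.010G012400, a pollen Ole e 1 and extensin family gene, from 37.7 CPM in wild type to 1.76 ± 0.70 CPM (SD, n = 2; log2 fold change -4.40, SE 0.33). The EP3 chitinase match Potri.019G093900 stood at a log2 fold change of -2.61 (SE 0.28) and the histone variant H2AX match Potri.018G042800 at -2.58 (SE 0.28). A glycine-rich protein gene, Potri.002G252200, stood at -2.13 (SE 0.21). The glutamine synthetase match GSR2, Potri.005G093200, stood at -2.10 (SE 0.40), and the photosystem II subunit PSBR match Potri.001G438600 at -2.08 (SE 0.45).

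Histones package DNA. Each of the 30 genes listed for DNA replication and histones is described as a histone, so the list holds no replication gene. Of these 30, 30 were called lower and 0 higher, with a median log2 fold change of -0.99. Their median lay at the 0.01 percentile of random lists of the same size and expression. Potri.007G013300, a histone superfamily gene, fell from 917 CPM in wild type to 320 CPM in KD2 and 387 CPM in KD5. HTA12 (Potri.006G082300) fell from 1744 to 713 and 765 CPM, and the histone gene Potri.001G016900 from 308 to 114.2 and 122.8 CPM. The cell cycle list had 1 member, CYCD6;1 (Potri.004G032100), at a log2 fold change of -1.03.

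Of 125 listed genes matched by name as ribosomal proteins, 115 were called lower and 7 higher, with a median log2 fold change of -0.85. The match was meant for cytosolic ribosomal proteins but also took in plastid ones encoded in the nucleus, such as the PRPS17 match, and other genes such as the elongation factor match LOS1. The median lay at the 12.42 percentile of matched random lists, within their range. Those random lists could draw the ribosomal protein genes themselves, so this is not a comparison with other genes alone. The match of ribosomal protein L39, Potri.006G188500, fell from 497 CPM to 127 CPM in KD2 and 184 CPM in KD5. Potri.016G077200 (L40e) and Potri.012G086600 (S30) stood at log2 fold changes of -1.64 and -1.58. The list held 4 genes that match organelle genomes, of which 2 were called higher and 1 lower, among them Potri.013G136600 (L22) at a log2 fold change of 2.94. The ribosomal protein genes also differed between the RNAi libraries, with a median log2 ratio of KD2 to KD5 of -0.22. After loess normalization 50 were called lower.

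Of 56 listed photosynthesis genes, 49 were called lower and 5 higher, with a median of -0.87 at the 8.22 percentile of matched random lists, also within their range. The chlorophyll-binding protein CAB1 (Potri.005G239200) fell from 731 CPM to 260 CPM in KD2 and 274 CPM in KD5, and LHCB1.4 (Potri.005G239300) from 449 to 153 and 188 CPM. PSBR (Potri.011G142200) stood at a log2 fold change of -1.95, and the Rubisco small subunit RBCS1A (Potri.004G100000) at -1.35. Of the 5 called higher, 4 match the chloroplast genome. After loess normalization 26 were called lower.

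The list of organelle-encoded genes went the other way. Of its 34 members, 31 of which match an organelle-genome locus, 21 were called higher and 3 lower, with a median log2 fold change of 1.97. Besides the subunit C, Ycf1 and L22 matches, the nuclear-type match YCF37 (Potri.007G034300) stood at -1.41. The list differed between the RNAi libraries, with a median log2 ratio of KD2 to KD5 of 0.62. Whether these models are close enough to organelle sequence to take its reads was not examined, so their values are uncertain. The organelle, ribosomal protein and heat shock lists had been fixed beforehand as indicators of RNA quality. Whether RNA quality differed between wild type and the RNAi libraries was not tested.

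Of 17 listed ethylene and AP2/ERF factors, which regulate transcription in stress and development, 11 were called higher and 2 lower. Their median log2 fold change was 2.91, or 2.44 with the 7 genes at 0 in wild type set at their bound, and lay at the 99.99 percentile. It rested in part on KD5, since the median log2 ratio to wild type, with a prior count of 2, was 1.43 in KD2 alone and 2.35 in KD5 alone. The ethylene-responsive nuclear protein match Potri.001G464300 rose from 2.28 CPM to 11.8 CPM in KD2 and 13.1 CPM in KD5, and Potri.011G162400 from 6.67 to 14.7 and 19.3 CPM. ERF-1 (Potri.001G079900) fell, at a log2 fold change of -1.18. Loess normalization called 7 of these genes higher and DESeq2 0.

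Of 12 listed genes for flowering time, dormancy and meristem identity, 9 were called lower and 2 higher, with a median at the 25.72 percentile of matched random lists. DRM1 (Potri.004G047100), a dormancy-associated gene, fell from 3418 CPM to 1474 CPM in KD2 and 1478 CPM in KD5. SHOOT MERISTEMLESS (Potri.011G011100), which maintains the shoot meristem, fell from 149 to 67.2 and 89.2 CPM, and Potri.013G014900, a dormancy and auxin associated gene, from 838 to 501 and 470 CPM. Of 5 listed clock and photoperiod genes 4 were called lower, with a median at the 53.07 percentile and 2 called lower with size-only scaling. Among them were PIF1 (Potri.002G252800) at a log2 fold change of -0.78, COL2 (Potri.017G107500) at -0.69 and GRP8 (Potri.004G155300) at -0.62. The last was at -0.87 in KD2 alone and -0.40 in KD5 alone, and turned to 0.11 after loess normalization.

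Of the 14 genes given by identifier, 9 were tested and 1 was called, both over all genes and adjusted over the list alone. This was LHY1 (Potri.002G180800), a clock gene, at 29.4 CPM in wild type, 20.2 CPM in KD2 and 13.9 CPM in KD5 (log2 fold change -0.79, SE 0.24, edgeR adjusted p = 0.013). LHY2 stood at a log2 fold change of 0.01, PHYA at 0.05, PHYB1 at 0.54, PHYB2 at -0.12, AIL1 at -0.16, SVL at -0.08 and CENL1 at 0.69, and none of these was called. With size-only scaling AIL1, SVL and PHYB2 were above 0. EBB1 had 2, 2 and 7 counts in wild type, KD2 and KD5. FT1 and LAP1 had 1 count in wild type and 0 in the RNAi libraries, and FT2 and CEN2 had 0 in every library, so no difference was detectable at this depth.

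Among hormone lists, 4 of 4 gibberellin genes were called lower, including GASA1 (Potri.005G239100) at a log2 fold change of -1.24 and the gibberellin-regulated gene Potri.015G071500 at -1.36. Besides GASA1, the members are described as gibberellin-regulated family proteins, so the list holds no gibberellin synthesis or receptor gene. Of 4 abscisic acid genes 3 were called lower, namely HAI2 (Potri.001G245200 and Potri.009G037300) at -1.05 and -0.83 and HAI3 (Potri.001G092100) at -1.23, phosphatases induced by abscisic acid. Of 8 auxin genes 5 were called lower and 1 higher, with IAA14 (Potri.008G161200) at -1.95 and IAA7 (Potri.010G078300) at -0.63. The only cytokinin gene, the response regulator ARR12 (Potri.018G111300), rose by a log2 fold change of 1.32.

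Of 17 flavonoid and phenylpropanoid genes 15 were called lower and 1 higher, with a median log2 fold change at the 0.25 percentile of matched random lists. Chalcone synthase, the entry enzyme of flavonoid synthesis, was lower at Potri.012G138800 (-1.03) and Potri.003G176900 (-1.16). CYP98A3 was lower at Potri.016G031100 (-1.12) and Potri.006G033300 (-0.93). Of 21 cell wall loosening and pectin genes 15 were called lower and 1 higher, with a median at the 5.99 percentile, within the range of matched random lists. Among them were expansin EXPA4 (Potri.001G240900) at -1.08 and the pectin lyase-like genes Potri.003G076900 and Potri.006G122000 at -1.95 and -0.93. Of 11 callose and glucan genes 10 were called lower, with a median at the 26.59 percentile, among them PDCB3 (Potri.010G158900), a plasmodesmata callose-binding protein, at -0.89. The lowest adjusted p in this list belonged to Potri.010G029100 and Potri.008G200100, which are glutamine synthetases that share a symbol with a glucan synthase.

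The list of DNA methylation machinery had 3 members. The match of the histone methyltransferase SUVH5 (Potri.012G114400) rose from 6.83 CPM to 19.1 CPM in KD2 and 24.6 CPM in KD5. The match of the chromatin remodeller DDM1 (Potri.T120000) fell from 14.1 to 5.46 and 4.92 CPM. The remaining member was DRM1, which here is the dormancy-associated gene and not a methyltransferase.

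Of 12 cold and dehydration genes 6 were called lower and 5 higher, with RCI2A (Potri.005G002100) at -1.23, a late embryogenesis abundant gene (Potri.002G165000) at -1.05 and GSTF6 (Potri.T035400) at -1.13. Those called higher include the matches of the C-repeat binding factors CBF4 (Potri.012G134100) and CBF2 (Potri.001G110800). CBF4 had 0, 14 and 18 counts in wild type, KD2 and KD5, and CBF2 had 0, 9 and 15. Of 39 defence genes 15 were called lower and 11 higher, with PR4 (Potri.013G041600) at -0.98, PRB1 (Potri.T131500) at -1.38 and a thaumatin gene (Potri.001G237600) at -0.98. PRB1 was at -0.80 in KD2 alone and -2.29 in KD5 alone. Of 10 sugar and starch genes 5 were called higher and 3 lower, and the lowest adjusted p belonged to TPS21, a terpene synthase. Of 15 heat shock and chaperone genes 8 were called lower and 6 higher, with HSC70-1 (Potri.008G054600) at -0.89 and the DnaJ gene Potri.005G043200 at 1.10. Those called higher include Potri.008G066000 and Potri.010G191300, matched by the symbol HSPRO2. They are described as orthologs of a sugar beet gene and not as heat shock proteins or chaperones.

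Photosynthesis genes had been fixed beforehand as markers of green leaf tissue, and 56 were listed. Markers of the remaining tissues were few among the listed genes. Only listed genes carry names, so these numbers do not measure tissue content, and a difference in tissue between libraries was not tested. Of 4 secondary xylem genes 4 were called lower, with CESA7 (Potri.006G181900) at -1.30, LAC6 (Potri.014G100600) at -0.77 and XBCP3 (Potri.011G066900) at -0.84. XBCP3 is described as a xylem bark cysteine peptidase. Of 4 phloem genes 3 were called lower, at Potri.017G071000, Potri.001G340400 and Potri.012G090400. All 4 match the same Arabidopsis locus, AT3G01680, which has no symbol or description here, so they are not separate markers. Of 8 epidermis and cuticle genes 6 were called lower and 1 higher, with a median at the 26.57 percentile, and with LTP1 (Potri.004G086600 and Potri.016G135400) at -0.98 and -1.02 and PDF1 (Potri.002G060800) at -0.81. Medians of the auxin, cold, xylem, defence, sugar and heat shock lists also lay within the range of matched random lists, from the 16.53 to the 85.75 percentile, and those of gibberellin, abscisic acid and phloem genes, with 4 members each, lay at 1.64, 3.9 and 6.16. The list of floral organ identity had 1 called gene, SEP1 (Potri.001G301100), which here is stress enhanced protein 1.

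**Figure D2:**
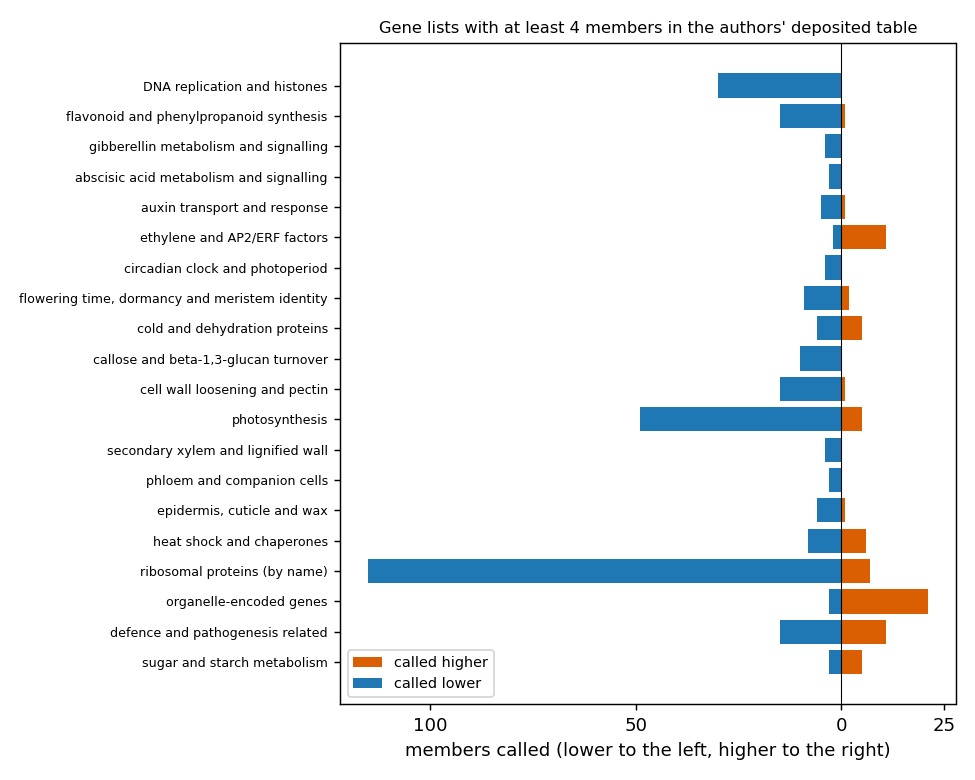
Number of genes called higher (to the right) and lower (to the left) in the RNAi libraries, for each list with at least 4 members in the authors' deposited table. The ribosomal protein list has 115 lower and 7 higher, and the organelle-encoded list has 3 lower and 21 higher.

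**Figure D3:**
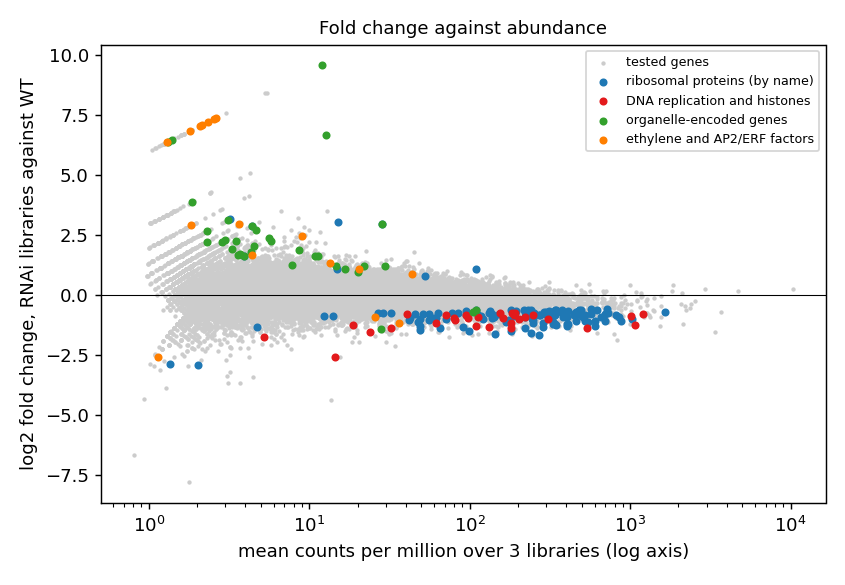
Log2 fold change of the RNAi libraries against wild type (vertical axis) over mean CPM in the 3 libraries (horizontal log axis), with each point a tested gene and 4 lists in colour. Values at the upper left are fitted changes of genes with 0 counts in wild type and are not bounds.

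The authors' deposited table lists 764 genes as higher and 1387 as lower in the KD lines. Of these 2151 genes 1923 (89.4%) were called here, 1923 of them with the same sign, and 228 were not called. Another 1091 calls were outside the table. The overlap was 47.7% with loess normalization, 26.6% with DESeq2 and 0 without a filter on low counts. The table was made from the same libraries and is not independent. An edgeR exact test with a common dispersion and no filter, chosen after seeing the data, differed from the table's log2 fold changes by at most 1.8e-05 and gave 2129 calls, 2129 of them listed.

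Each line was then set against wild type, with 1 library on each side and no test. Of the 1155 higher calls 1147 were above wild type in both RNAi libraries, and of the 1859 lower calls 1859 were below it in both. A change of at least 2-fold upward was seen in 1218 genes in KD2 and 1138 in KD5, with 640 shared. Unchanged lines that share the wild type library gave 40.2 in the mean of 100 simulations (22 to 65), and independent lists would share 60. For downward changes the numbers were 1200 in KD2 and 771 in KD5 with 433 shared, against 19.2 in the simulations (8 to 34) and 40.1 for independent lists. Across the 23089 genes, which are not independent replicates, the log2 ratios correlated at r = 0.73, against 0.46 in 100 simulations of unchanged lines that share the wild type library. Their covariance was 0.28 against a simulated 0.06, and the sign was shared by 78.4% of genes against 65.6%. The control is a single library and cannot be split, so part of the excess may come from it. The simulations gave every gene the common dispersion of 0.013. They put 389 genes at least 2-fold apart between KD2 and KD5, against 1002 observed, so the simulated shared changes may be too few.

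**Figure D4:**
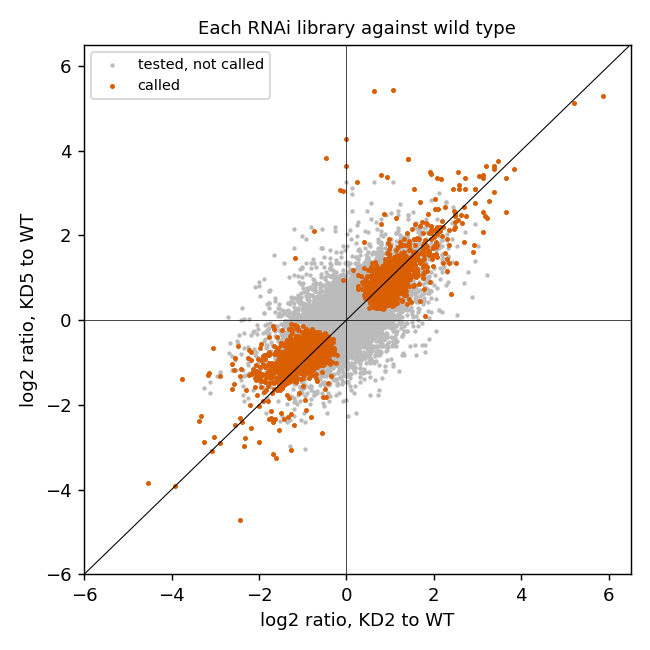
Log2 ratio to wild type in KD2 (horizontal axis) and KD5 (vertical axis), with each point a tested gene and called genes in orange. The diagonal marks equal ratios, and 1147 of 1155 higher calls lie above 0 on both axes.

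KD2 and KD5 differed from each other by at least 2-fold in 1002 genes, 408 higher in KD2 and 594 higher in KD5, against 389 in the simulation. Among genes with at least 5 CPM on average the number was 234. The log expression values correlated at 0.97 between KD2 and KD5, 0.94 between wild type and KD2 and 0.95 between wild type and KD5.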

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

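Both results given here were singled out because the RNAi libraries lay on opposite sides of wild type, and the differences were not tested. For LHY2 (Potri.014G106800), the log2 ratio to wild type was 0.30 in KD2 and -0.36 in KD5, so that KD5 lay at -0.67 relative to KD2. For PHYA (Potri.013G000300), the ratios were -0.06 and 0.15, and KD5 lay at 0.21 relative to KD2. Names rest on published identifiers that the files do not pair with them.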

How the results depend on the processing

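The loess normalization and the authors' own settings were chosen after seeing the data. Without a filter 0 genes were called (5051 at an unadjusted p under 0.05), so the overlap with the authors' deposited table and the ribosomal, photosynthesis, histone and AP2/ERF calls were each 0. The DESeq2 Wald test gave 595 calls, 6.7% of them higher, an overlap of 26.6% and 0 AP2/ERF calls, with 24314 adjusted p-values left as NA. Loess normalization gave 1175 calls, an overlap of 47.7%, and 50 ribosomal, 26 photosynthesis and 7 AP2/ERF calls. Of the 31 list counts, 22 moved by over 1.5 times with loess, 23 with DESeq2, 31 without a filter, 19 at 2-fold, 7 with size-only scaling and 3 each with limma-voom and at an adjusted p under 0.01. At an adjusted p under 0.01 there were 1712 calls. Requiring at least 2-fold left 924 calls, 50.8% of them higher, an overlap of 42.5%, and 36 ribosomal, 20 photosynthesis and 14 histone calls. With size-only scaling 75.5% of calls were higher and PtaDML10 was called at 0.874. Genes at least 2-fold apart between KD2 and KD5 numbered 633 with a prior count of 5 and 234 among genes of at least 5 CPM. Apart from the stricter thresholds, which pass fewer genes by construction, the cause was not tested.

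Median log2 fold changes of the histone, photosynthesis and ribosomal lists went to -0.77, -0.647 and -0.634 with size-only scaling and to -0.771, -0.557 and -0.559 with loess. Without replicate 1 or 2 the histone median ran from -1.147 to -0.978 and the AP2/ERF median from 1.429 to 2.345.

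Of the named genes, 77 lost their call without a filter, 39 with DESeq2, 15 with loess and 6 with size-only scaling. Stricter thresholds took the call from 25 at 2-fold and from 3 at an adjusted p under 0.01. Some log2 fold changes near 0, of genes not called, changed sign. AIL1 (Potri.002G114800) went to 0.055 with size-only scaling and 0.097 with loess, SVL (Potri.007G010800) to 0.144 and 0.027, and PHYB2 (Potri.010G145900) to 0.101 with size-only scaling. LHY2 (Potri.014G106800) went to -0.003 with DESeq2 size factors, -0.008 without a filter and under the authors' settings, -0.006 with DESeq2, -0.034 with limma-voom, -0.080 with loess and ran from -0.364 to 0.302 without 1 replicate. PHYA (Potri.013G000300) ran from -0.062 to 0.147 without 1 replicate. GRP8 (Potri.004G155300), a called gene, went from -0.616 to 0.108 with loess. PtaDML10 stayed above 0 in every alternative, from 0.448 without replicate 2 to 0.874 with size-only scaling, with 0.802 without replicate 1. Robust quasi-likelihood, exact and likelihood ratio tests moved no list count by over 1.5 times. No list median changed sign in any alternative run. No paired analysis was possible because the groups share only 1 replicate number. The percentiles among random lists take no account of correlation between genes, and a list test with an estimated correlation was not run, since genes outside the authors' deposited table carry no annotation here. With 1 wild type library and a floor near 0.488 CPM there, low genes limit what can be seen.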

Other observations

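Groups described in this part, and the tests other than the splits, were chosen after the data were seen. Of 32 listed jasmonate and early stress response genes, 24 were called higher and 5 lower, with a median log2 fold change of 2.49, or 2.34 with the 8 genes at 0 in wild type set at their bound. The median log2 ratio to wild type, with a prior count of 2, was 1.61 in KD2 alone and 2.13 in KD5 alone. JAZ1 (Potri.003G068900), a repressor of jasmonate signalling, had 11, 18 and 108 counts in wild type, KD2 and KD5, and JAZ10 (Potri.003G165000) had 13, 33 and 102. The calmodulin-like gene CML37 (Potri.002G001400) had 0, 24 and 20 counts, and ZAT10 (Potri.002G119300) had 2, 18 and 37. LOX2 (Potri.001G015400), a lipoxygenase of jasmonate synthesis, went the other way with 106, 16 and 33.

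Of 44 listed pentatricopeptide, tetratricopeptide and ARM repeat genes, 34 were called higher and 4 lower, with a median of 1.33 at the 99.96 percentile of matched random lists. Of 11 listed mitochondrial transcription termination factor genes, 9 were called higher and 0 lower, with a median at the 92.73 percentile, within the range of matched random lists. Of 11 ubiquitin genes, 11 were called lower, with a median at the 19.91 percentile, also within that range. Of 9 proteasome genes, 7 were called lower and 1 higher, with a median at the 1.51 percentile. Of 73 genes for short proteins of other functions, 63 were called lower and 5 higher, with the metallothionein MT2A (Potri.006G085200) at -1.54.

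The first pattern is that the PtaDML10 locus was not lower in the libraries labelled KD2 and KD5. Counting error does not hide a reduction, since the exact interval of the ratio starts at 1.16. For a wild type label exchanged with an RNAi library, 1 of 2 exchanges, that with KD5, would put both RNAi libraries below wild type. It follows from the order of the libraries at the locus, where wild type was lowest and KD5 highest, and is no evidence for that exchange. Against that exchange, setting wild type apart gave 3014 calls and setting KD5 apart 4, and KD2 and KD5 correlated most closely, at 0.97, with wild type and KD2 least, at 0.94, but it stays open because 1 library can stand apart for other reasons. Reads from the RNAi transgene, and an identifier that differs from the gene targeted, stay open and untested.

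The second pattern is that ribosomal protein, histone and photosynthesis genes were lower. Bias that follows transcript abundance alone stays open. The median of these 211 genes went from -0.88 (quartiles -1.11 and -0.75, median SE 0.16) to -0.61 (-0.88 and -0.36, 0.16) after loess normalization. Lower calls went from 194 to 97 as the folds shrank. Members had been selected for change on these libraries, so a median that stays below 0 cannot decide the question. Against random lists matched on expression, the ribosomal and photosynthesis medians lay within range (12.42 and 8.22 percentiles), while that of histones lay at 0.01. The random lists could draw genes of these same lists, so lying within range does not show that other genes of like abundance fell as much. With size-only scaling, 179 of the 211 were called lower, the fewest of the 4 scalings. Members had been selected for change on these libraries, and these scalings shift all genes nearly alike. The count therefore shows only that the choice among the 4 does not undo most of the calls. A scaling error beyond the range of these methods stays open. Lower recovery of short transcripts may contribute and stays open with no transcript lengths used here, since 92.6% of called genes for short proteins of other functions were lower, with a median at the 0.18 percentile, and 66.7% of 6 called aminoacyl-tRNA synthetase and initiation factor genes against 65.7% of all called listed genes with an Arabidopsis locus. Variation between libraries of one genotype (-0.22 between KD2 and KD5 over ribosomal protein genes) and an effect of the RNAi lines cannot be told apart, because wild type has 1 library.

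The third pattern is that jasmonate and early stress genes were higher. Handling or wounding of the buds behind the KD5 library alone is argued against as the whole cause, since the 32 listed members had a median log2 ratio of KD2 to wild type of 1.61 (lower quartile 0.55). In 100 simulations with KD2 at the level of wild type, the authors' settings called only 4 to 11 members, against 32 observed. The members so called had medians from -0.55 to 0.89. Of the 24 called higher, 22 were above wild type in KD2 (median 1.69, lower quartile 1.03) and 24 in KD5 (median 3.09), and 17 were higher in KD5 than in KD2. These 24 were called in a fit that includes KD2, so their values there are not independent support. A difference in handling between wild type and both RNAi libraries, and an effect of the lines, stay open and untested.

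Splits of the 3 libraries into 1 and 2 are too few for a share under 0.05. Setting wild type apart gave 3014 calls, and 1 of the 3 splits gave as many, with 4 calls in the highest of the others.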
